A study of Homo sapiens with 6 samples.

How the data were processed

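RNA sequencing libraries were compared from HCT116 cells, an established human colorectal cancer line, that carried a doxycycline-inducible short hairpin RNA (shRNA) against CAPG. The labels describe 3 libraries without doxycycline and 3 libraries after 3 days with doxycycline at 100 ng/µl, the unit as the labels give it. Total RNA was extracted with TRIzol, per the labels' protocols. Strandedness, read length and depth are not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

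The authors' deposited table holds 1 value per gene and library for 60643 genes, with an Ensembl identifier, a symbol and a locus. The deposited values were treated as FPKM (fragments scaled by transcript length and library size) because of how they behave, since the header names no unit. They were not whole numbers, their sums per library were not equal to a fixed total, and the lowest values of single-exon genes scaled inversely with gene length. Bowtie, BWA, STAR, Cufflinks, RSEM and kallisto are named without versions or roles, per the submitters' processing notes, so which of them made the FPKM values is not given in the sources used here. The same notes name the build hg19. The loci in the table were instead those of GRCh38 with starts counted from 0. Of 39331 versioned identifiers found in GENCODE 29, 39321 had the GENCODE locus after that offset, and coordinates are therefore given on GRCh38, counted from 1. FPKM divides out library size and transcript length, so a transcript class that takes up more of a library lowers the values of other genes, and genes with near-identical copies can exchange reads.

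Depth was estimated from the spacing of the lowest values in 3640 single-exon genes longer than 1000 bases, where 1 fragment gives a fixed step. The estimate lay between 14100000 and 18100000 fragments per library, under the assumption that whole fragments were counted over the annotated exon length. At that depth 3 fragments in a 1 kb transcript correspond to 0.165 to 0.213 FPKM. These limits cover counting error only.

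Before the data were examined, the groups, the test, the gene lists, the rule for named genes and a first set of alternatives were fixed. The fixed plan held a test for count tables and limma for FPKM, and the limma branch applied. Genes with at least 1 FPKM in at least 3 libraries were tested (14475 genes) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using the trended, robust empirical Bayes fit with the group as the only term. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. CAPG was also compared by an exact permutation test.

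Of the 33 gene lists, written from textbook knowledge, 28 had at least 5 tested members and were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry were alternatives. Fry asks whether the genes of a list move, on balance, in a single direction, and does not compare the list with other genes. The lists covered p53 targets and regulators, pro-apoptotic and anti-apoptotic genes, ferroptosis-promoting and ferroptosis-restraining genes, stress responses, metabolism, cell cycle, mitochondrial and ribosomal genes, cytoskeleton, epithelial and mesenchymal genes, signalling targets, and markers of fibroblasts, leukocytes, endothelium, hepatocytes and intestinal differentiation.

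Named genes were CAPG, the 8 highest and the 8 lowest log2 changes among genes past the threshold that reached a mean of 1 FPKM in the higher group, carried a gene symbol and had groups that did not overlap, and up to 4 members of each list with the smallest p-values, or up to 2 where none passed. Genes known only by a clone name were counted as having no symbol. Further members named in the text (CDKN1A, MDM2, BAX, BBC3, GPX4, ACSL4, NFE2L2, ATF4, ASNS, CA9, NDRG1, GAPDH, LDHA, CCNE1, CCNE2, MT-CO1 and the remaining members of short counts) were chosen after their values were seen. Results of some genes that these rules name are not reported here.

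The fit was tested on simulated data with the means and spreads of the 14475 tested genes, in 5 simulations of 200 changed genes each. It recovered 8% of genes changed 1.25-fold, 74.8% at 1.5-fold, 94.4% at 2-fold and 96% at 4-fold, and 6.05% of its calls were false. With a rise of 0.25 planted in the p53 target list, camera gave that list an adjusted p of 6.08e-33, or 0.0176 with an estimated correlation, and called 0 other lists. The simulated noise was independent between genes, while the correlation estimated in the real data reached 0.848 (cytosolic ribosomal proteins). The simulation therefore cannot show how often camera at the preset correlation calls unchanged lists of correlated genes. A search of 7-base words in 3' untranslated regions (UTRs) was tested in 50 simulations with a planted log2 drop of 0.1, and ranked the planted word first in 100% of them. That search used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

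The alternatives were no filter, a filter at 5 FPKM, pseudocounts of 0.1 and 0.5, a non-robust fit, the replicate number as a block, each library left out in turn, an adjusted p threshold of 0.01 and a minimum log2 change of 1. Added after the data were seen were libraries scaled to equal totals, median-of-ratios scaling, a correction for transcript length and GC content (loess, span 0.3, on the longest GENCODE transcript), protein-coding genes only, and leaving out genes with a certain 7-base word. No read-level analysis was made, and no other shRNA, cell line or protein measurement was analysed here.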

Results

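The data were gene expression values (FPKM) from 6 RNA sequencing libraries of HCT116 colorectal cancer cells carrying a doxycycline-inducible shRNA against CAPG, an actin filament capping protein of the gelsolin family. The cells were kept without doxycycline (3 libraries) or given 100 ng/µl for 3 days (3 libraries). The estimated depth was 17800000, 17500000 and 14100000 fragments in replicates 1, 2 and 3 without doxycycline and 17700000, 18100000 and 18000000 with it. Between 14257 and 14526 genes reached 1 FPKM per library. FPKM values summed to between 521832 and 536037 in 5 libraries and to 586911 in replicate 3 with doxycycline. On the second principal component (21% of the variance) that library lay at 17.19 and the other libraries with doxycycline at -12.24 and -13.05, while replicates 1, 2 and 3 without doxycycline were spread as well, at 14.05, 2.60 and -8.55. The first component (38.1%) separated the groups. The design has a single comparison, with against without doxycycline, which the series title connects to p53, apoptosis and ferroptosis. Libraries given doxycycline without this shRNA were not analysed here, so the comparison covers the drug and the shRNA together.

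CAPG (ENSG00000042493, chromosome 2, 85394753 to 85418432, GRCh38) was at 57.2 ± 3.75 FPKM without doxycycline and at 8.73 ± 1.08 FPKM with it (SD, n = 3 each), so that 15.3% of its level was left. It had the smallest adjusted p of all tested genes (log2 change -2.59, SE 0.10, limma adjusted p = 7.24e-06). The groups did not overlap, and the exact permutation p was 0.1 (two-sided), the smallest that 3 against 3 libraries allow. After CAPG, the genes that fell most were RAB38, a small GTPase of melanosome and lysosome-related organelle transport (11.8 ± 0.462 to 3.23 ± 0.198 FPKM, log2 -1.60), DHRS2, a short-chain dehydrogenase (19.7 to 6.55, log2 -1.46), and TCOF1, the nucleolar protein treacle (34.8 to 12.3, log2 -1.42). Their limma adjusted p-values were 1.57e-04, 2.61e-04 and 1.7e-04. FUBP3 (log2 -1.14) and the proton pump subunit gene ATP6V0E1 (log2 -1.12) fell as well. The mitochondrial protease subunit gene IMMP2L was also called lower (16.6 ± 4.54 to 6.04 ± 3.03 FPKM, log2 -1.38, SE 0.31, adjusted p = 0.0427), but the call was lost in 5 of the 6 fits that left out a library, with adjusted p up to 0.118.

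Among the genes that rose most with doxycycline were KRT15, a basal epithelial keratin (7.93 ± 1.13 to 21.7 ± 4.44 FPKM, log2 1.33, SE 0.15), CHAC1, a glutathione-degrading enzyme (5.66 ± 1.12 to 15.4 ± 1.84, log2 1.31, SE 0.14), and DDIT3, the stress-induced transcription factor CHOP (16.5 to 35.4 ± 5.85, log2 1.05, SE 0.11). All 3 had a limma adjusted p of 0.00228. The sulfotransferase gene SULT2B1 rose from 3.67 to 8.54 FPKM (log2 1.05) and the RNA-binding protein gene RBM15 from 13.8 to 29 FPKM (log2 1.0). The other members of the 8 highest were the processed pseudogene CHMP4BP1 (0.766 to 4.13 FPKM), the 7SK-related RN7SKP80, listed at 0 in all 3 libraries without doxycycline, and the small nucleolar RNA gene SNORA73B (7.25 to 16.6 FPKM). These 3 can share reads with related sequences and are uncertain, and SNORA73B lost its call when any of the 3 libraries without doxycycline was left out (adjusted p 0.0943, 0.107 and 0.0757). Among genes past the threshold, the largest positive change belonged to AC245033.3, a pseudogene known by a clone name (1.3 to 14.2 FPKM, log2 2.83).

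Across all 14475 tested genes, 534 were higher and 691 lower with doxycycline, 8.46% of the genes. Most changes were small. Their median size was 0.50 on the log2 scale, and 12 higher and 18 lower genes reached a log2 change of 1. In 4994 genes (34.5%) the 2 groups did not overlap, against 10% by chance. At an unadjusted limma p under 0.05 there were 4036 of the 14475 tested genes. The unadjusted counts of the gene lists given below are to be read against that share of all genes. The number of calls depended on the libraries used: it was 512, 242 and 699 without replicates 1, 2 and 3 of the group without doxycycline, and 627, 390 and 1000 without replicates 1, 2 and 3 of the treated group.

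**Figure D1:**
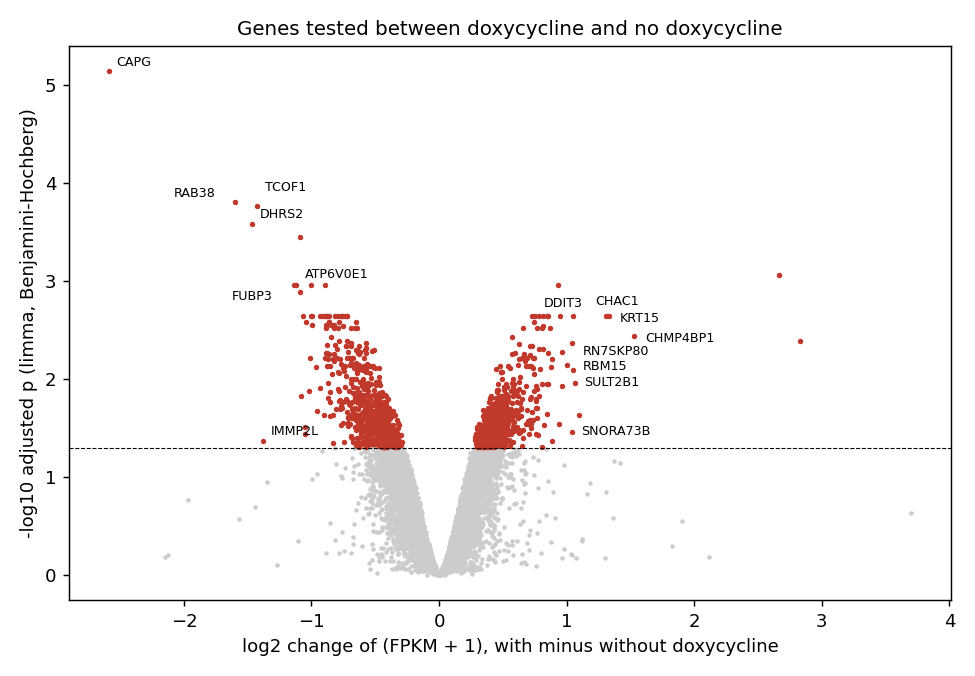
Log2 change of (FPKM + 1) against the -log10 adjusted p from limma, each point a tested gene, with genes past the adjusted p threshold of 0.05 in red and of these the 8 highest and 7 of the 8 lowest not known by a clone name labelled. CAPG lies apart at the upper left, at a log2 change of -2.59.

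Most p53 target genes did not pass the test, as was true of all tested genes (8.46% called). Of 40 tested p53 targets, 4 rose and 0 fell by limma, where 534 of all 14475 tested genes rose and 691 fell. At an unadjusted limma p under 0.05 the counts were 8 and 2, and adjusted over the list alone they were again 4 and 0. The genes that rose were SESN2, a stress-induced inhibitor of mTORC1 signalling (4.79 ± 0.339 to 7.37 ± 0.753 FPKM, log2 0.53), PHLDA3, an AKT inhibitor (12 to 18.5, log2 0.58), the fructose bisphosphatase TIGAR (7.5 to 11.2, log2 0.53) and the exonuclease AEN (24.4 to 32.5, log2 0.41), with limma adjusted p of 0.0216, 0.0303, 0.031 and 0.0348. Widely used p53 targets did not pass the test: CDKN1A, which encodes the cell cycle inhibitor p21, was at 143 ± 8.81 and 136 ± 10.1 FPKM (adjusted p = 0.597), MDM2 at 64.2 ± 6.97 and 72.0 ± 10.7 FPKM (0.441), and BAX at 50.6 ± 5.66 and 47.7 ± 2.76 FPKM (0.639). The median log2 change of the list was 0.06, and camera did not call it (adjusted p = 0.23, or 0.542 with an estimated correlation). The counts depended on the fit. After correction for length and GC content 7 p53 targets were called higher and 1 lower, where 1163 of all tested genes were higher and 1239 lower. Without replicates 1, 2 and 3 of the untreated group 3, 0 and 1 of the p53 targets were called higher, and 1 without each treated replicate. With libraries scaled to equal totals TIGAR missed the threshold (0.0572). Of 14 tested p53 regulators, RCHY1, a ubiquitin ligase for p53, rose (12.8 to 18.6 FPKM, log2 0.51, adjusted p = 0.0122, and 0.0534 without untreated replicate 2 or 0.0528 without treated replicate 2), and 0 fell, with 1 higher and 2 lower at an unadjusted p under 0.05. Adjusted over the list alone 1 was higher and 1 lower, and camera did not call the list (0.948).

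**Figure D2:**
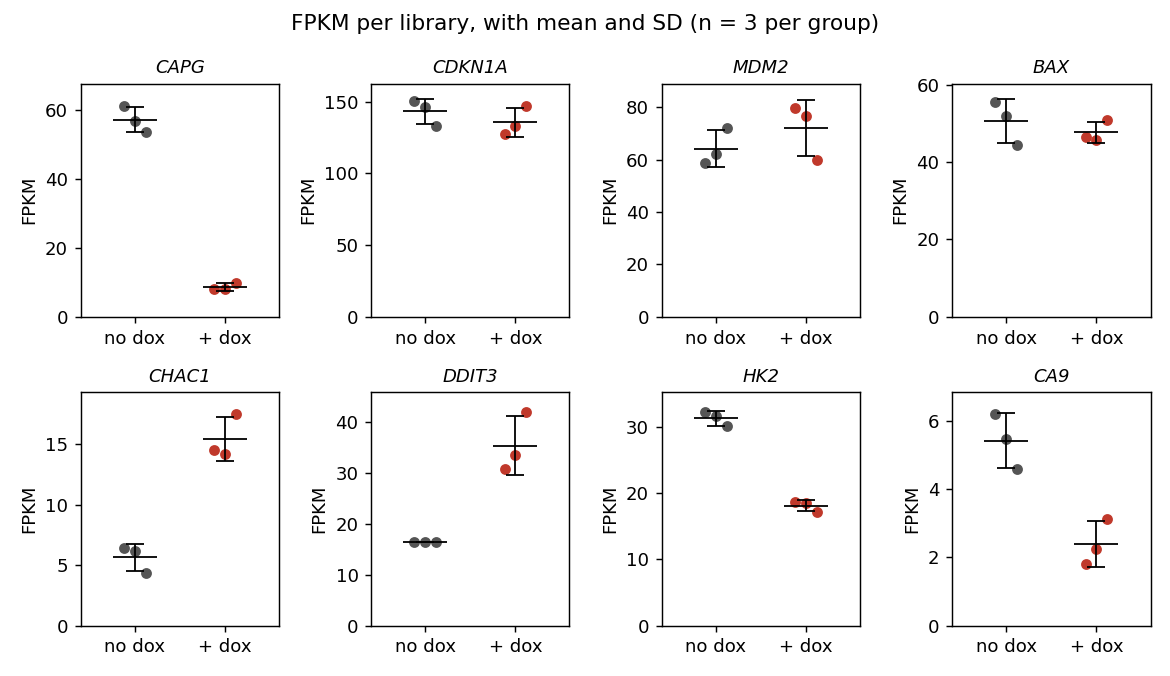
FPKM in each library of CAPG, CDKN1A, MDM2, BAX, CHAC1, DDIT3, HK2 and CA9 without (grey) and with (red) doxycycline, where the horizontal bar is the mean and the whiskers are the SD (n = 3 per group). The groups are apart for CAPG (57.2 and 8.73 FPKM), CHAC1, DDIT3, HK2 and CA9, and overlap for CDKN1A, MDM2 and BAX.

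Most genes of the cell death machinery did not pass the test either. Among 29 tested pro-apoptotic genes 1 rose and 0 fell, where 534 of all 14475 tested genes rose and 691 fell. Adjusted over the list alone the counts were the same, 1 and 0. At an unadjusted limma p under 0.05 they were 9 and 2, where 4036 of all 14475 tested genes had such a p. BBC3, which encodes PUMA, was at 9.46 ± 0.915 and 12 ± 0.887 FPKM (adjusted p = 0.0844). Of 14 tested anti-apoptotic genes 1 rose, the HSP70 co-chaperone gene BAG3 (39.4 to 50.1 FPKM, log2 0.34, adjusted p = 0.0452), and 0 fell, with 6 and 2 at an unadjusted p under 0.05 and 1 and 0 adjusted over the list alone. Camera called neither list (adjusted p = 0.163 and 0.145, with medians of 0.08 and 0.18), while fry called the anti-apoptotic list (0.0123). Without untreated replicate 2 and without treated replicate 2 the pro-apoptotic genes called higher numbered 0, and after the length and GC correction 4. The BAG3 call was lost in each fit that left out a library other than untreated replicate 1 (adjusted p up to 0.142) and with equal totals (0.0581).

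Ferroptosis is cell death from iron-dependent lipid peroxidation, which glutathione and the peroxidase GPX4 hold back. Of 23 tested genes that promote it, CHAC1 rose and the transferrin receptor gene TFRC (189 ± 12.6 to 145 ± 6.97 FPKM, log2 -0.39) and the polyamine acetyltransferase gene SAT1 (660 ± 27.5 to 525 ± 35.5 FPKM, log2 -0.33) fell. Of 27 tested genes that restrain it 5 rose: HSPA5, the endoplasmic reticulum (ER) chaperone BiP (111 ± 2.62 to 175 ± 13.2 FPKM, log2 0.66), HSPB1, a small heat shock protein (182 to 299, log2 0.72), SLC7A11 (7.27 to 11.6, log2 0.61) and SLC3A2 (74.6 to 106, log2 0.50), the chains of the cystine importer, and NFE2L2, which encodes NRF2 (46.7 to 59.5, log2 0.34). The glutathione synthetase gene GSS fell from 30.4 ± 2.85 to 19.8 ± 1.39 FPKM (log2 -0.59, adjusted p = 0.0101). Values that did not pass the test were those of GPX4 (129 ± 7.35 and 146 ± 20.3 FPKM, adjusted p = 0.34) and ACSL4 (25.7 ± 2.72 and 23.7 ± 0.869 FPKM, 0.496). Adjusted over the list alone, 2 promoting genes were higher and 2 lower, and 6 restraining genes were higher and 1 lower. Camera called neither list (adjusted p = 0.912 and 0.246). Both medians were 0.01, and camera gave the promoting list a downward direction against its positive median. The TFRC call was lost without untreated replicates 2 and 3 and treated replicate 2 (0.113, 0.0707 and 0.0673), the SAT1 call in each fit that left out a library other than treated replicate 3 (up to 0.165), and the SLC7A11 call without untreated replicates 1 and 2 and treated replicates 1 and 2 (up to 0.0864). Without untreated replicates 1 and 2 and treated replicate 2, 3 restraining genes were called higher in each fit.

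Many stress response genes rose. ATF4 is the transcription factor of the integrated stress response, and of 38 tested ATF4 and integrated stress response genes 14 rose and 3 fell; adjusted over the list alone, 20 were higher and 4 lower. Those that rose included CHAC1, DDIT3, the pseudokinase gene TRIB3 (11.7 ± 1.49 to 20.2 ± 1.46 FPKM, log2 0.74), the asparagine synthetase gene ASNS (75.9 to 105, log2 0.46) and ATF4 (269 to 339, log2 0.33, adjusted p = 0.0479). The 3 that fell were DDIT4, an mTORC1 inhibitor also induced by hypoxia (155 ± 7.04 to 104 ± 7.86 FPKM, log2 -0.57), PYCR1 (log2 -0.47) and CTH (log2 -0.53), enzymes of proline and cysteine synthesis. The median of the list was 0.27 (camera adjusted p = 1.47e-05), with an adjusted p = 0.535 with an estimated correlation. Without untreated replicates 1, 2 and 3 the genes of this list called higher numbered 8, 4 and 8, and without treated replicates 1, 2 and 3 they numbered 8, 7 and 10. The genes called lower numbered 1 without untreated replicates 1 and 2 and treated replicates 1 and 2, 2 without untreated replicate 3 and 3 without treated replicate 3.

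Some chaperone genes of the ER and of the cytosol rose. Of 20 tested ER unfolded protein response genes 5 rose, HSPA5, DNAJB11 (55.0 ± 1.95 to 82.4 ± 5.65 FPKM, log2 0.57), HERPUD1 (26.5 to 37.7, log2 0.49), MANF (69.4 to 92.3, log2 0.40) and SDF2L1 (log2 0.56), and 0 fell by limma, with 12 higher and 0 lower at an unadjusted p under 0.05; adjusted over the list alone 6 were higher, and after the length and GC correction 8 were called higher. Of 15 tested heat shock genes 7 rose and 0 fell, with 12 higher and 0 lower at an unadjusted limma p under 0.05, and adjusted over the list alone 12 were higher. HSPB1, HSPA1B (34.2 ± 3.84 to 51.5 ± 1.49 FPKM, log2 0.58), DNAJA1 (131 to 183, log2 0.47) and HSPA4 (135 to 185, log2 0.45) were among them, HSPA1B with the reservation that it can share reads with the near-identical HSPA1A. Camera called the ER list (median 0.23, adjusted p = 2.32e-05) and the heat shock list (median 0.29, adjusted p = 1.25e-07), and each had an adjusted p = 0.535 with an estimated correlation. Leaving out untreated replicate 2 lowered the counts most, to 2 ER genes and 2 heat shock genes; without untreated replicates 1 and 3 the heat shock genes called higher numbered 3 and 4, without treated replicates 1 and 2 they numbered 4 and 4, and without untreated replicate 3 and treated replicate 2 the ER genes numbered 3 and 3. The calls of MANF (up to 0.122), HERPUD1 (0.0541), DNAJA1 (0.0792) and HSPA4 (0.0846) were among those lost without untreated replicate 2. The stress lists share members with the ferroptosis and p53 target lists. CHAC1, SLC7A11, SLC3A2 and SESN2 are also in the ATF4 list, HSPA5 in the ER list and HSPB1 in the heat shock list. The counts of these lists are therefore not independent.

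Genes of glycolysis and the hypoxia response were lower in part. Of 31 tested, 13 fell and 0 rose by limma, with 20 lower and 0 higher at an unadjusted p under 0.05, and adjusted over the list alone 19 were lower. They included the hexokinase gene HK2 (31.3 ± 1.14 to 18.1 ± 0.815 FPKM, log2 -0.76), the peptide hormone gene ADM (56.6 ± 3.11 to 33.9 ± 1.6, log2 -0.72), PFKFB4, which sets fructose 2,6-bisphosphate (22.4 to 11.8, log2 -0.87), the aldolase gene ALDOC (82.1 to 43.8, log2 -0.88) and CA9, a carbonic anhydrase induced by hypoxia (5.42 to 2.39, log2 -0.93). Abundant glycolytic genes did not pass the test, with GAPDH at 2525 ± 137 and 2521 ± 252 FPKM and LDHA at 975 ± 23.3 and 877 ± 60.6 FPKM. The median of the list was -0.32 (camera adjusted p = 1.06e-09), with an adjusted p = 0.535 with an estimated correlation. Without untreated replicate 2 the genes called lower numbered 7, and the other fits that left out a library called between 9 and 14.

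Genes for entry into S phase were lower in part. Of 30 tested G1/S and DNA replication genes 6 fell and 0 rose (11 lower and 1 higher at an unadjusted limma p under 0.05), and adjusted over the list alone 8 were lower and 1 higher. Those that fell included the uracil glycosylase gene UNG (34.9 to 23.7 FPKM, log2 -0.54), E2F2 (8.34 to 5.07, log2 -0.62), the licensing factor gene CDT1 (29 to 18.7, log2 -0.61) and the cyclin genes CCNE2 (log2 -0.62) and CCNE1 (log2 -0.51). The median was -0.15 (camera adjusted p = 0.0018), with an adjusted p = 0.535 with an estimated correlation. Of 35 tested G2/M and mitosis genes, PLK1 (61.7 to 79.6 FPKM, log2 0.36) and CCNB1 (147 to 184 FPKM, log2 0.32) rose and the phosphatase gene CDC25B fell (61.8 ± 6.50 to 39.0 ± 2.52 FPKM, log2 -0.65); adjusted over the list alone 3 were higher and 1 lower, and after the length and GC correction 5 were called higher and 4 lower. Camera did not call this list (adjusted p = 0.23). PLK1 lost its call in all 6 fits that left out a library (adjusted p up to 0.12), and CCNB1 in each except that without treated replicate 3 (up to 0.125).

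**Figure D3:**
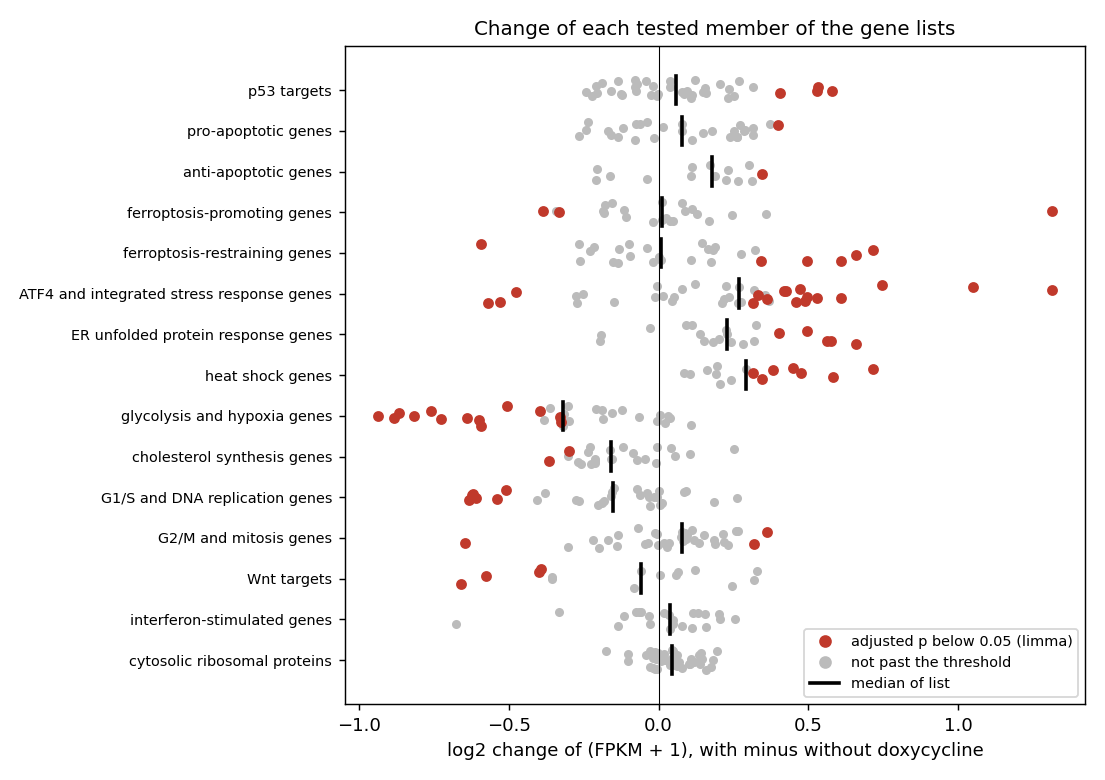
Log2 change of (FPKM + 1) of each tested member of 15 gene lists, with members past the limma adjusted p threshold of 0.05 in red, the others in grey and the median of each list as a black bar. The medians of the heat shock genes (0.29) and the ATF4 and integrated stress response genes (0.27) lie to the right, and that of the glycolysis and hypoxia genes (-0.32) to the left.

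Genes of cholesterol synthesis had a median of -0.16 over 24 tested. Of these 2 fell, the sterol sensor gene INSIG1 among them (58.2 to 47.1 FPKM, log2 -0.30), and 0 rose, with 7 lower and 1 higher at an unadjusted limma p under 0.05; adjusted over the list alone 2 were lower and 0 higher, and after the length and GC correction 6 were called lower. Camera called the list lower (adjusted p = 0.00986), with an adjusted p = 0.535 with an estimated correlation and 0.0606 without untreated replicate 2. Nuclear genes of oxidative phosphorylation and mitochondrial ribosomal proteins both had a median of 0.16, over 37 and 34 tested genes. NDUFA6 (45.0 to 57.8 FPKM), MRPL27 (63.5 to 92.3) and MRPL15 (54.3 to 69.2) rose and the Rieske protein gene UQCRFS1 fell (34.6 to 26.3). Adjusted over the list alone, 0 oxidative phosphorylation genes and 2 mitochondrial ribosomal genes were higher and 0 were lower in either, and at an unadjusted limma p under 0.05 there were 12 and 7 higher and 2 and 0 lower. After the length and GC correction 6 oxidative phosphorylation genes were called higher and 2 lower, and 3 mitochondrial ribosomal genes higher. Camera called both higher (adjusted p = 0.00983 and 0.00575), each with an adjusted p = 0.831 with an estimated correlation, and without treated replicate 3 neither was called (0.255 and 0.172). Of the genes named here, NDUFA6 lost its call in all 6 fits that left out a library (up to 0.183), UQCRFS1, MRPL15 and INSIG1 in 5 of them (up to 0.157, 0.106 and 0.172), and MRPL27 in 4 (up to 0.0886).

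Markers of other cell types were mostly near the floor in both groups. Below 1 FPKM in every library were 10 of 12 fibroblast markers, 14 of 16 leukocyte markers, 9 of 10 endothelial markers, 10 of 12 hepatocyte markers and 27 of 29 genes of intestinal differentiation. Of the few that could be tested, CD68, a lysosomal protein of macrophages, fell (3.94 ± 0.476 to 2.01 ± 0.38 FPKM, log2 -0.72, adjusted p = 0.0167) and SERPINA1, which encodes alpha-1 antitrypsin, rose (1.12 ± 0.132 to 2.83 ± 0.208 FPKM, log2 0.86, adjusted p = 0.00546). FBLN1 (11.2 and 10.4 FPKM), COL1A1 (9.06 and 8.37), ESAM (7.19 and 8.76) and CA2 (49.8 and 54.4) did not pass. The CD68 call was lost without untreated replicate 2 (0.0733) and treated replicate 2 (0.0512).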

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

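Chosen after the data were seen were equal totals, median-of-ratios scaling, the length and GC correction, protein-coding genes only and the removal of 7-mer carriers; the other alternatives were set before the data were examined. CAPG kept its direction and its call under each alternative, and 0 named genes changed direction past the threshold. Higher and lower genes numbered 53 and 100 with no filter (more genes tested), 69 and 142 with the replicate block, 58 and 130 at an adjusted p under 0.01, 12 and 18 at a log2 change of at least 1, and 1163 and 1239 after the length and GC correction. Leaving out each library gave 85 to 403 higher and 157 to 597 lower genes, with fewer samples in each fit. Same-numbered libraries did not deviate together (correlations -0.0433, 0.00936 and -0.0231), and pairs of unlike numbers lay between -0.0856 and 0.102. With 3 libraries per group this cannot decide whether equal numbers shared a preparation, and the labels do not say. Of the 211 blocked calls, 208 were among the 1225. The higher share of calls was 43.6% in the reported fit against 33.9% with equal totals, which moved the median of all genes to -0.05. With an estimated correlation camera gave 0.535 for the G1/S, ATF4, ER, glycolysis and hypoxia, cholesterol and heat shock lists and 0.831 for both mitochondrial lists. The shared 0.535 comes from the adjustment over the 28 lists, after which none passed. Before it, camera with an estimated correlation gave p = 0.026 (ER), 0.0477 (glycolysis and hypoxia), 0.0849 (heat shock), 0.109 (G1/S), 0.129 (cholesterol) and 0.134 (ATF4). Fry gave 0.0123 for the anti-apoptotic and Wnt lists, 0.0297 for the gelsolin family, and 0.418 and 0.373 for oxidative phosphorylation and mitochondrial ribosomal genes. For lists that camera called at the preset correlation, fry gave 0.0123 (ER, and glycolysis and hypoxia), 0.0208 (heat shock), 0.0271 (G1/S), 0.0297 (ATF4) and 0.0488 (cholesterol). It gave 0.0754 for p53 targets. Fry does not compare a list with other genes. Leaving out a library gave 0.00467 to 0.0606 for cholesterol synthesis, 0.0162 to 0.417 for cytosolic ribosomal proteins (called without treated replicate 1, and without treated replicate 2 at 0.0462), 0.000576 to 0.255 for oxidative phosphorylation and 0.000437 to 0.172 for mitochondrial ribosomal genes. The median of hepatocyte markers was -0.026 with no filter, which adds members near the floor. Of 82 named genes past the threshold, 39 kept the call without each library in turn, 40 lost it without at least 1, and 3 kept it in each fit that tested them but were not tested when a treated library was left out. Of the 82, 53 lost the call with no filter and 45 with the block. Where not stated, the cause was not tested. RLE and total-count normalization of read counts, DESeq2 and voom, planned for count tables, were not run because the table holds no counts. By the estimated depth, 3 fragments on a transcript of 1 kb equal 0.165 to 0.213 FPKM, which limits genes near that level.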

Other observations

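Tests chosen only after the result was seen were those of a single treated library behind the stress response and mitochondrial lists and that of doxycycline itself; the tests of site type and base composition were set after the 7-mer had been found. Targets of the Wnt pathway, which is active in HCT116 cells through a beta-catenin mutation, were lower in part. Of 15 tested, MYC (95.3 ± 3.98 to 60.1 ± 3.77 FPKM, log2 -0.66, limma adjusted p = 0.00302), SOX9 (27.9 ± 0.854 to 18.4 ± 0.145, log2 -0.57), the adhesion receptor gene CD44 (210 to 159, log2 -0.40) and EPHB2 (9.64 to 7.09, log2 -0.39) fell and 0 rose, with 3 higher and 6 lower at an unadjusted p under 0.05. Without treated replicate 3, and also after the length and GC correction, 3 Wnt targets were called higher. Adjusted over the list alone 6 were lower and 3 higher, and camera did not call the list (0.23). CD44 lost its call without untreated replicates 1 and 2 (0.0543 and 0.0832) and treated replicate 2 (0.0561), and EPHB2 in all 6 fits that left out a library (up to 0.114). Of 31 tested MYC and ribosome biogenesis genes MYC alone fell and 0 rose, with 3 higher and 2 lower at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (camera 0.625). Of 43 cytosolic ribosomal proteins 0 changed by limma, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera 0.23), and 3 were called lower without treated replicate 3.

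Among genes of the actin cytoskeleton, SRF, the transcription factor of many actin genes, fell (12.3 ± 0.887 to 6.23 ± 0.221 FPKM, log2 -0.88, adjusted p = 0.00228), as did VCL, for vinculin (50.9 to 36.6, log2 -0.47), while the kinase gene LATS2 rose (3.68 to 5.72, log2 0.52). The actin and SRF list of 29 tested was not called (camera 0.726, median 0.01 and mean -0.04), with 1 higher and 4 lower adjusted over the list alone. Of 16 genes of the gelsolin family and actin capping other than CAPG, 0 passed by limma or adjusted over the list alone, with 3 higher and 1 lower at an unadjusted p under 0.05 (camera 0.23). IER3, an NF-kB target, rose from 168 ± 9.26 to 309 ± 43.5 FPKM (log2 0.87, adjusted p = 0.00304) and CXCL8 from 0.896 to 1.83 FPKM (log2 0.58). CXCL8 was called in none of the fits that left out a library (0.0517 to 0.148). Of the 12 tested NF-kB and inflammatory genes 0 fell. At an unadjusted p under 0.05, 4 were higher and 0 lower, and adjusted over the list alone 2 and 0 (camera 0.23). Of 23 interferon-stimulated genes 0 passed by limma or adjusted over the list alone, with 0 higher and 2 lower at an unadjusted p under 0.05 (camera 0.726). Of 23 NRF2 targets SLC7A11 and OSGIN1 rose and ABCC3 fell, with the same counts of 2 and 1 adjusted over the list alone (camera 0.986), while the NRF2 targets called lower numbered 0 to 3 when a library was left out, 3 without treated replicate 3. In the epithelial list of 23, ELF3 fell (91.9 to 60.7 FPKM, log2 -0.59) and EPCAM rose (190 to 241, log2 0.34), with 1 and 1 adjusted over the list alone (camera 0.377), and in the mesenchymal list of 13 TGFB1 rose (15.3 to 20.6 FPKM) and CD44 fell, with 1 higher and 2 lower adjusted over the list alone (camera 0.438). Of 29 lysosome and autophagy genes CTSL (51.3 to 71.6 FPKM) and ATP6V1H (20.7 to 29) rose and GPNMB (5.40 to 2.29, log2 -0.96), TPP1 (20.5 to 13.8) and WIPI1 fell, with 4 and 3 adjusted over the list alone (camera 0.23). The histone gene H2BC4 rose (2.12 to 3.76 FPKM) among 7 replication-dependent histone genes, 0 of which fell. In that list 1 was higher and 0 lower at an unadjusted p under 0.05, and likewise 1 and 0 adjusted over the list alone (camera 0.633). MT-ND1 (2056 to 2677 FPKM) and MT-ND2 (2803 to 3512) rose among 13 mitochondrially encoded genes and 0 fell, with MT-CO1 at 4561 and 4298 FPKM. In that list 3 were higher and 0 lower at an unadjusted p under 0.05, and 2 and 0 adjusted over the list alone (camera 0.134). After the length and GC correction the counts called higher and lower were 4 and 3 for NRF2 targets, 3 and 4 for the actin and SRF list, 2 and 1 for the gelsolin family, 3 and 2 for epithelial genes, 1 and 3 for mesenchymal genes and 6 and 3 for lysosome and autophagy genes. Calls lost in 2 or more of the fits that left out a library were those of VCL (up to 0.0582), LATS2 (0.0812), SLC7A11 (0.0864), OSGIN1 (0.0893), ABCC3 (0.0887), EPCAM (0.138), TGFB1 (0.095), CD44 (0.0832), H2BC4 (0.0896), MT-ND1 (0.127) and MT-ND2 (0.178), and ATP6V1H (0.0888) and CTSL (0.0719) lost theirs without untreated replicate 2.

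Part of the fall of other transcripts may be an off-target effect of the shRNA through its seed, a hypothesis found and tested on the same data. Among 16154 7-mers in the 3' UTRs of 11737 genes other than CAPG, GACCTCC went with the most negative shift (z = -11.9, against -4.56 as the bound from 100 shuffles); it lay in 145 of 601 lower genes (24.1%) and in 7.17% of the others, shares that follow in part from its choice on the same values. The search covered a single 3' UTR per gene and no coding sequence. Sites elsewhere in a transcript, or in other transcript forms of these genes, were therefore not looked for. RAB38, TCOF1 and FUBP3 carry the 7-mer followed by A in the searched 3' UTR. There DHRS2 and IMMP2L lack even the inner 6-mer, and ATP6V0E1 has only that 6-mer followed by A. Among the lower list members named above, GSS, SRF and ELF3 carry the 7-mer followed by A, and E2F2 and CDT1 carry it without that A. An off-target fall therefore stays open for them. It stays open as well for ATP6V0E1, UNG, CDC25B, SAT1 and ABCC3, which have only the inner 6-mer followed by A. Carriers of that site type also shifted downward. In the searched 3' UTRs, MYC, SOX9, CD44, GPNMB and TPP1 lack the inner 6-mer. The shift was graded over site types, with medians of the uncorrected log2 change of -0.03 for the inner 6-mer alone, -0.07 with a following A, -0.10 for the 7-mer and -0.14 for GACCTCCA. The z values and the trend over site types were instead computed after removal of trends with 3' UTR length and GC content, with extreme changes limited. That trend had a permutation p = 0.0001 (one-sided, the smallest 10000 shuffles can give, with no allowance for the choice of the 7-mer). Base composition alone is argued against by a margin in z of 5.954 to the closest of the reverse complement and 207 7-mers of equal base counts. GACCTCCA occurs once in 11 of 15 CAPG transcripts, 8 of them with the site in a coding sequence and 3 with no coding sequence annotated (chromosome 2, 85401293 to 85401300, GRCh38, exon 5 of 10 in the transcripts with 10 exons). However, 3.76% of all 8-mers and 13.3% of the tested 7-mers occur in CAPG. The sequence of the shRNA is not given in the sources used here, and a microRNA with this seed stays open. In the searched 3' UTRs, 456 of the lower genes and all 13 lower glycolysis and hypoxia genes lack the 7-mer. Of these 456 genes, 81 carry the inner 6-mer alone, 90 carry it followed by A and 285 lack it. Genes with the 6-mer followed by A were called lower in 8.82%, against 3.56% of genes without the 6-mer. As to chance, 1 of the 10 splits of the 6 libraries, the real split, gave 1225 genes and the highest other gave 4, and 10 splits are too few for a share under 0.05. The other splits also mix treated and untreated libraries in each group. Any treatment effect then widens the spread within groups, so their low counts do not measure what chance gives.

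The rise of ATF4 and integrated stress response genes could come from the loss of CAPG, from an off-target effect of the shRNA, from the drug, or from the libraries. Treated replicate 3 as the whole source is argued against, since without it the median was 0.23 (SE 0.04) against 0.27 with all libraries. That SE comes from the spread between the genes of the list, treated as independent, and does not measure the spread between libraries. A trend with transcript length or GC content is argued against by a median of 0.25 after correction for both. Doxycycline itself, which inhibits mitochondrial translation and could start this response, cannot be told apart from the loss of CAPG, because 0 libraries given doxycycline without the shRNA were analysed. An off-target effect of the shRNA cannot be told apart from the loss of CAPG either, because no other shRNA was analysed here.

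The small rise of nuclear-encoded mitochondrial genes is less secure. Over the mitochondrial ribosomal and oxidative phosphorylation genes together (71 genes) the median lay 0.16 above that of all genes, and after the length and GC correction 0.13 above it, which argues against that trend as the whole source. Without treated replicate 3 it was 0.083 (SE 0.0177, again from the spread between genes and not between libraries), and both lists then lost their call. How far the rise may rest on that library stays open. An effect of doxycycline on mitochondria was not tested.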
